A study of Caenorhabditis elegans with 2 samples.

How the data were processed

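TF ChIP-seq had been done on 2 biological replicates of L3 larvae of strain OP231, in which ZK546.5 carries a GFP-FLAG tag, per the labels. Each replicate had a list of calls on builds ce10 and ce11, and both had been pooled for a further list and for a thresholded set, per the deposited file notes. According to those notes each list was made from alignments of the replicate, or of both replicates together, and 1 control file that was the same for both. The thresholded set was derived from the pooled list and both replicate lists by the irreproducible discovery rate (IDR) procedure. The aligner, the peak caller, the antibody and the IDR threshold were not given in the sources used here.

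The deposited lists gave for each call an interval, a summit, a signal value and a q-value field. The deposited signal values are the caller's own measure of each call, and their scale differs between lists, so they were used to rank calls within a list and in correlations. Ratios between replicates were read only relative to those of other peaks. The deposited q-value field was treated as a score because its scale was not stated, and it ran from 1.36 to 2.05 in the thresholded set and from 0.0291 to 2.05 in the pooled list. Each replicate list and the pooled list ended at exactly 30000 calls, so they were cut by number, and binding and background were not separated in their weaker part. No read counts were in the files, so the depth of each replicate is unknown. Binomial intervals are exact (Clopper-Pearson) at 95% and cover counting error over peaks or genes only.

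Gene 5′ ends came from the Ensembl release 115 annotation of ce11, with 46926 genes of which 19985 are protein-coding. Names on the mitochondrial genome were taken from the RefSeq annotation of the same assembly by reciprocal overlap. Coordinates are 1-based on ce11, and ce10 lists were compared only with ce10 lists. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and blastn 2.17.0.

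Replicate agreement was measured as the share of the strongest calls of replicate 1, as many as there were thresholded peaks, with such a call of replicate 2 whose centre lay within 200 bp. It was set against 1000 random placements on the same chromosomes. Signal values at each thresholded peak were those of the nearest call within 200 bp of the pooled summit, and Spearman's rho was tested with 100000 permutations. Thresholded peaks were compared with the 29710 pooled calls that overlapped none of them, which had gone through the same processing. Closeness to a 5′ end (500 bp), location on X, gene lists and words of 6 bases (100 bp around the summit) were tested with two-sided Fisher's exact tests, and GC content (200 bp) with a permutation test. Odds ratios were computed with 0.5 added to each cell. Benjamini-Hochberg adjustment was applied over the lists, the words and the chromosomes, each as 1 family.

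The gene list and word tests were first tested on simulated data. With 15 proteasome genes planted among 250 random protein-coding genes, the planted list was found in 20 of 20 draws and 0 of 580 other list tests passed. With a word planted in the windows of 261 random calls, it was found in 20 of 20 draws, and 6 of 41600 word tests passed for words that did not overlap it. At least 15 of 33 proteasome genes were thus marked, against 4 of 33 in the real data, and genes were drawn independently. Real peaks can be shared by neighbouring genes and differ in GC content from the other calls. The simulations therefore do not give the power or the false-call rate of the real comparisons.

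The main tests, gene lists, the rule for named items and 61 alternatives were fixed before the data were examined. Afterwards, 13 alternatives and the pooled test of tissue and stage lists were added. The rule named the gene with the nearest 5′ end for the 25 strongest peaks, ZK546.5 and unc-119, up to 4 members with the highest signal for each list past an adjusted p of 0.05, and the 3 leading words in each direction. Other genes named were chosen after their values were seen. The alternatives changed the number of calls compared, the distance or overlap that counts as shared, the windows, the build, the comparison set and the replicate used. With 1 replicate left out, the strongest 261 calls of the other were compared with its remaining calls. Mitochondrial peaks were kept in the main comparisons. No mock immunoprecipitation or expression data were used here.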

Results

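Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map where the protein ZK546.5 sits on the genome of third-stage (L3) larvae of the nematode Caenorhabditis elegans. The worms carried an integrated transgene, wgIs231, that expresses ZK546.5 with a GFP-FLAG tag at its C terminus, in strain OP231. Chromatin came from whole animals of both sexes and was sheared by sonication. The series held 2 biological replicates of 1 group and no second condition, so agreement between the replicates and the content of the peaks were the comparisons that the design allowed. Each replicate was represented by a list of 30000 calls and so was the pooled data, and the submitters' thresholded set held 261 peaks on build ce11. Sequencing depth was unknown because the files gave no read counts. Peaks and genes are not independent replicates, so the tests across them describe this experiment only.

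Most of the strongest peaks lay in intergenic sequence just upstream of genes. The highest deposited signal value, 1408, was at a summit on chromosome I at position 14469353, in intergenic sequence 147 bp upstream of ekl-4 and 250 bp upstream of rps-20, which encodes a small-subunit ribosomal protein and is transcribed in the opposite direction. The second, with a signal of 1294 on chromosome V at 10897375, was 232 bp upstream of sec-61.G, a subunit of the channel that passes new proteins into the endoplasmic reticulum. Next on chromosome I came a summit 56 bp downstream of the 5′ end of the non-coding gene Y65B4BR.10 (signal 1241), also 247 bp upstream of wwp-1, and 1 that was 341 bp upstream of icd-2 (signal 1202), which encodes a part of the nascent polypeptide-associated complex. Further summits were 168 bp upstream of hsr-9 (signal 1138), 139 bp upstream of the alpha-tubulin gene tba-2 (1134), 5 bp upstream of the ATP synthase gene atp-1 (1115), 313 bp upstream of sqd-1 (1057) and 9 bp upstream of the elongation factor gene eef-2 (1023). Of the 25 strongest peaks, 20 were nuclear, and all 20 lay within 500 bp upstream of the nearest protein-coding 5′ end.

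Among the remaining nuclear peaks of these 25, summits lay 67 bp upstream of the G protein gene egl-30 (signal 852), 174 bp upstream of the cohesin-release gene wapl-1 (851) and 422 bp upstream of ntl-2 (847). Others lay 475 bp upstream of Y17G7B.20 (760), 250 bp upstream of dpm-3 (645), 67 bp upstream of tmem-107 (640) and 58 bp upstream of ant-1.1 (634), an adenine nucleotide translocator of the mitochondrial inner membrane. At 4 further peaks the nearest annotated 5′ end was that of a small or non-coding RNA gene. These were C08F8.13 (24 bp, signal 866), the piRNA gene 21ur-13751 (120 bp, 849), mir-5549 (17 bp, 824) and AH9.7 on chromosome X (117 bp, 807). The nearest protein-coding 5′ ends there were those of F01G4.6, vig-1, rfc-4 and rpl-11.2. The other 5 of the 25 were mitochondrial, nearest to a tRNA-Leu gene (signal 1023), ND4 (798), ND5 (791), the large ribosomal RNA gene (642) and a tRNA-Ser gene (586).

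The 2 replicates shared most of their strongest calls. Of the 261 strongest calls of replicate 1, 154 (59.0%) had a call among the 261 strongest of replicate 2 with its centre within 200 bp. After random placement on the same chromosomes the mean was 4.68% and the highest of 1000 draws 6.90% (permutation p = 0.001, the smallest these draws can give). The share was 39.7% with 2 times as many calls and 21.5% with 5 times as many. With nuclear calls only, a setting added after the values were seen, 143 of 261 (54.8%) were shared. The random mean was then 0.114% and the highest draw 1.53%. Replicate 1 held 185 of the 261 thresholded peaks (70.9%, 95% exact binomial interval 65.0 to 76.3) among its strongest 261 calls, and replicate 2 held 214 (82.0%, 76.8 to 86.5). Across the 248 thresholded peaks with a call in both lists, Spearman's rho between the signal values was 0.67 (permutation p = 1e-05, the smallest that 100000 permutations can give, two-sided). These peaks were selected by the submitters on the same replicates, so the correlation is not an independent measure of repeatability. Both replicate lists were called against the same control file, so random placement is not the value without binding, and the overlap does not show that the shared calls came from the immunoprecipitation. All 261 thresholded peaks were also the 261 strongest calls of the pooled list.

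**Figure D1:**
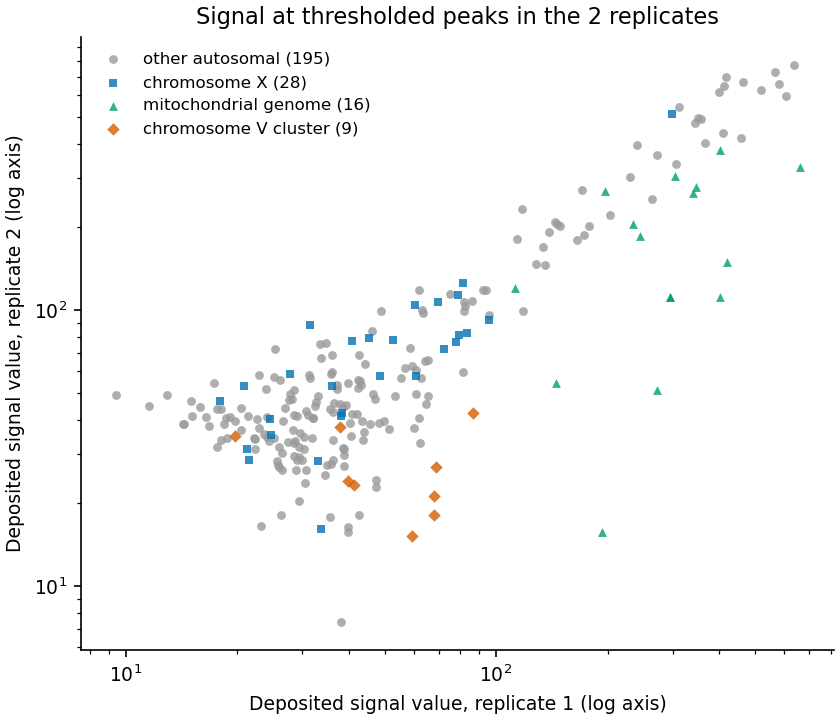
Deposited signal value of each thresholded peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale). Points are the 248 peaks with a call within 200 bp in both lists, marked by location; 8 of the 9 chromosome V cluster points have a higher ratio of replicate 1 to replicate 2 than the median of the other nuclear peaks.

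Thresholded peaks were concentrated at gene starts. A summit lay within 500 bp of an annotated 5′ end at 215 of 261 thresholded peaks (82.4%, 95% interval 77.2 to 86.8), against 10025 of the 29710 pooled calls that overlapped no thresholded peak (33.7%, 33.2 to 34.3). The odds ratio was 9.10 (two-sided Fisher's exact test, p = 3.18e-58). It was 8.45 without the mitochondrial peaks, 4.21 with replicate 1 alone and 5.18 against the strongest other calls. Counting nuclear peaks and protein-coding genes alone, the shares were 166 of 235 (70.6%) and 6135 of 29710 (20.6%). Of those 166 summits, 157 (94.6%) were upstream of the nearest coding 5′ end, compared with 57.3% of the other calls at coding 5′ ends. At 63 of the 166 protein-coding genes began on both strands within 500 bp of the summit. The median distance from a nuclear summit to a protein-coding 5′ end was 269 bp, against 1589 bp for the other calls. Nuclear summits were in intergenic sequence at 180 of 235 peaks (76.6%), in introns at 19, in non-coding genes at 19, in untranslated exons at 11 and in coding exons at 6. Many C. elegans transcripts are trans-spliced, so an annotated 5′ end can lie downstream of the true start of transcription.

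**Figure D2:**
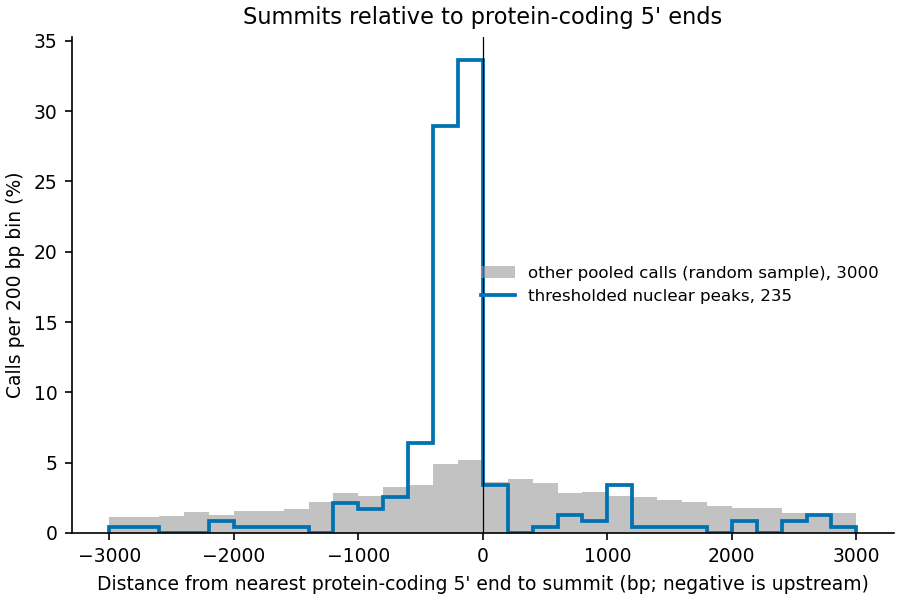
Distance in bp from the nearest protein-coding 5′ end to the summit (x axis, negative is upstream) against the percent of calls in each 200 bp bin (y axis). The outline gives the 235 thresholded nuclear peaks and the grey area a random sample of 3000 other pooled calls; the peaks pile up in the 500 bp upstream of the 5′ end.

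Ribosomal protein genes stood out among the 34 gene lists that had been fixed before the data were examined. A thresholded summit lay within 500 bp of the 5′ end of 31 of 81 ribosomal protein genes (38.3%, 95% interval 27.7 to 49.7), against 1.07% of the other protein-coding genes (odds ratio 57.5, adjusted p = 3.19e-37, Fisher's exact test with Benjamini-Hochberg adjustment over the lists). The members with the highest pooled signal were rps-20 (1408), rps-19 (1138), rpl-11.2 (807) and rps-23 (645). These 31 genes had 29 peaks between them, and each gene had its summit upstream, at 67 to 459 bp with a median of 284 bp. With a window of 250 bp, 6 of 81 had a peak (7.41%, odds ratio 12.3, Fisher's exact test, adjusted p = 0.000892). With assignment to the nearest gene alone, 12 of 81 had one (14.8%, odds ratio 25.9). The rest of the 31 thus lay by a summit that was nearer to the 5′ end of another gene. This held for each of the members named above.

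Other parts of the protein production and turnover machinery were also over-represented. Among translation factor genes, 6 of 39 had a peak (15.4%, against 1.19% of other protein-coding genes; Fisher's exact test, adjusted p = 8.22e-05), led by eef-2 (signal 1023), eef-1A.1 (824), iff-2 (350) and eif-3.C (121). Among proteasome genes, 4 of 33 had one (12.1%, odds ratio 12.5, Fisher's exact test, adjusted p = 0.00571), namely pbs-1 (301), rpn-3 (79.0), rpn-11 (71.1) and pbs-2 (52.1). The lists were not separate throughout, as the pbs-2 peak was also that of the translation factor gene eif-6. The rpn-3 peak was also that of the heat shock protein gene hsp-110. Small nucleolar RNA genes, whose products guide the modification of ribosomal RNA, had a peak at 13 of 346 (3.76%, against 0.754% of all other genes of any kind, odds ratio 5.32, Fisher's exact test, adjusted p = 6.50e-05), with F39B2.14 (640), H06I04.9 (516), F54E7.10 (193) and Y24D9A.9 (77.7) the strongest. Against protein-coding genes, a comparison added after the values were seen, the odds ratio was 3.27 (Fisher's exact test, adjusted p = 0.00555). At 6 of these 13 the same peak also lay at a ribosomal protein gene. The proteasome call was lost in the strongest 130 peaks, with nearest-gene assignment and with either replicate alone (Fisher's exact tests, adjusted p = 0.0594 for replicate 2 and 0.199 for replicate 1). The snoRNA call was lost in the strongest 130 peaks, with nearest-gene assignment and with replicate 1 alone (Fisher's exact test, adjusted p = 0.0603), and its odds ratio rose to 8.82 at 1000 bp. The translation factor call was lost at 250 bp (Fisher's exact test, adjusted p = 0.182).

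Lists of tissue and stage genes held no peak. The 10 lists for germline, body wall muscle, pharynx, intestine, epidermis and seam, neurons, glia, vulva and somatic gonad, heterochronic and molting genes had 295 distinct members, and none had a summit within 500 bp. At the share over all protein-coding genes (244 of 19985, 1.22%), 3.60 members with a peak would have been found by chance, and the shortfall did not pass the threshold (two-sided Fisher's exact test, p = 0.0549). This pooled test was not among those fixed beforehand, and its p-value depends on which lists are pooled. The lists of sperm genes (0 of 72) and vitellogenin genes (0 of 6) were not in it. For single lists a count of 0 allowed wide ranges. Among the 10 pooled lists the upper bound reached 21.8%, for the 15 glia genes, and for the vitellogenin genes it was 45.9%. No member of the innate immunity list had a peak among 314 genes, although this did not pass the adjustment (Fisher's exact test, p = 0.0359, adjusted p = 0.152). Neuropeptide (0 of 102) and homeobox genes (0 of 89) were likewise without a peak where 1.25 and 1.09 would have been found by chance, and cuticle collagen genes had 1 in 175. Nuclear-encoded respiratory chain and ATP synthase genes (3 of 47, Fisher's exact test, adjusted p = 0.111), histone genes (3 of 72, adjusted p = 0.219) and heat shock protein genes (2 of 22, adjusted p = 0.142) did not pass the threshold. Heat shock protein genes passed at 1000 bp (odds ratio 16.3, Fisher's exact test, adjusted p = 0.00241), and both they and respiratory chain genes passed with the 5′ end of every annotated transcript (Fisher's exact tests, adjusted p = 0.0158 for each). Respiratory chain genes also passed in the strongest 130 peaks (Fisher's exact test, adjusted p = 0.0335).

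**Figure D3:**
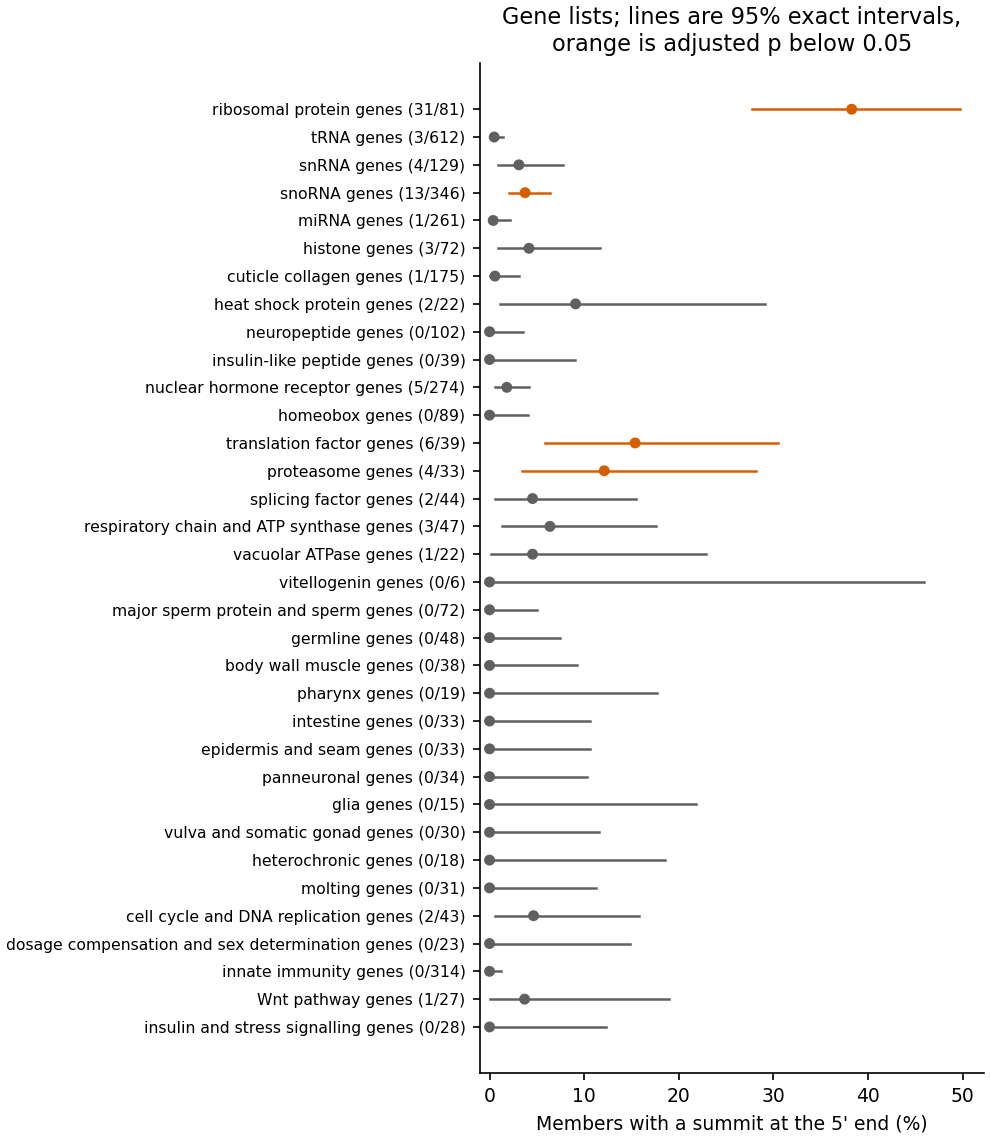
Percent of each list's members with a thresholded summit within 500 bp of the 5′ end (x axis), for 34 gene lists (y axis, members with a peak and list size in brackets). Points are shares, lines 95% exact binomial intervals and orange marks an adjusted p below 0.05; the ribosomal protein list has the highest share at 38.3%.

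The sequence under the summits was rich in G and C. In 200 bp centred on the summit, mean GC content was 40.2% ± 9.81 (SD, 261 peaks) at thresholded peaks and 31.4% ± 6.87 (SD, 29710 calls) at the other calls, a difference of 8.78 percentage points (permutation p = 1e-05, two-sided). Among nuclear calls at gene 5′ ends alone, the difference was 10.5 points. It was 5.56 points against random positions, 5.74 with replicate 1 alone and 4.35 in 400 bp. Of 2080 words of 6 bases, each counted with its reverse complement in 100 bp around the summit, 440 were more frequent and 160 less frequent at thresholded peaks (adjusted p below 0.05). ACGCAG occurred at 18.4% of peaks and 1.64% of other calls (odds ratio 13.6, Fisher's exact test, adjusted p = 8.30e-31). GACGCA occurred at 17.2% and 1.67% (odds ratio 12.3), and CGAGAC at 18.4% and 2.06% (odds ratio 10.8). The words most depleted were AAAAAA (26.4% and 57.9%), AAAATT (28.7% and 59.9%) and TGAAAA (15.3% and 43.1%). Against calls matched on GC content and nearness to a 5′ end, 197 words were more and 69 less frequent, and the odds ratios of the 3 leading words were 4.70, 4.97 and 5.55. The leading word there was ACCGTA (odds ratio 7.47, Fisher's exact test, adjusted p = 1.66e-16), which also led in the strongest 130 peaks and against the strongest other calls. Against those calls the odds ratios of ACGCAG, GACGCA and CGAGAC were 5.53, 4.25 and 5.42. With replicate 1 alone they were 8.98, 7.06 and 5.32, and GCGCAC led.

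Peaks were unevenly spread over the chromosomes. Of all 261 peaks, chromosome I held 56 (21.5% of peaks against 15.7% of other calls, Fisher's exact test, adjusted p = 0.0232), while chromosome V held 27 (10.3% against 18.7%, adjusted p = 0.00107) and X 28 (10.7% against 17.6%, adjusted p = 0.00724). Chromosome III held 52, chromosome IV 37 and chromosome II 35, and these did not pass the adjustment. Without the mitochondrial peaks, an alternative added after the values were seen, chromosome III passed (22.1% against 15.1%, Fisher's exact test, adjusted p = 0.00884). X was also compared with the autosomes alone. Of the 235 nuclear peaks, 28 were on X (11.9%, 95% interval 8.07 to 16.8), against 17.6% of the other nuclear calls (odds ratio 0.64, two-sided Fisher's exact test, p = 0.0247). That call was lost in the strongest 130 peaks (odds ratio 0.99, Fisher's exact test, p = 1), with either replicate alone (odds ratios 0.71 and 0.77) and against the strongest other calls (0.70). It turned in direction among calls farther than 500 bp from a protein-coding 5′ end (odds ratio 1.66, Fisher's exact test, p = 0.0884). Among calls within that distance the lower share on X was more marked (9 of 166 against 761 of 6135, odds ratio 0.43, Fisher's exact test, p = 0.00531). This split by distance was added after the values were seen. Peaks on X also sat in other places. Only 9 of the 28 (32.1%, 15.9 to 52.4) were within 500 bp of a protein-coding 5′ end, against 157 of 207 autosomal peaks (75.8%, 69.4 to 81.5), a comparison chosen after the values were seen (Fisher's exact test, p = 7.53e-06).

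All 26 pooled calls on the mitochondrial genome were in the thresholded set, with a median signal of 458, and together the peaks covered 54.2% of that genome. A call lay within 200 bp in both replicate lists for 16 of the 26. On chromosome V, 10 of the 27 peaks lay within 11613 bp, between 1618810 and 1630422. That stretch carries 5 nuclear hormone receptor genes in a row, nhr-179, nhr-117, nhr-110, nhr-237 and nhr-238. The peaks at their 5′ ends had signals from 129 at nhr-179 to 52.7 at nhr-117. Over the whole nuclear hormone receptor list, 5 of 274 genes had a peak (Fisher's exact test, adjusted p = 0.956), and all 5 were these neighbours.

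**Figure D4:**
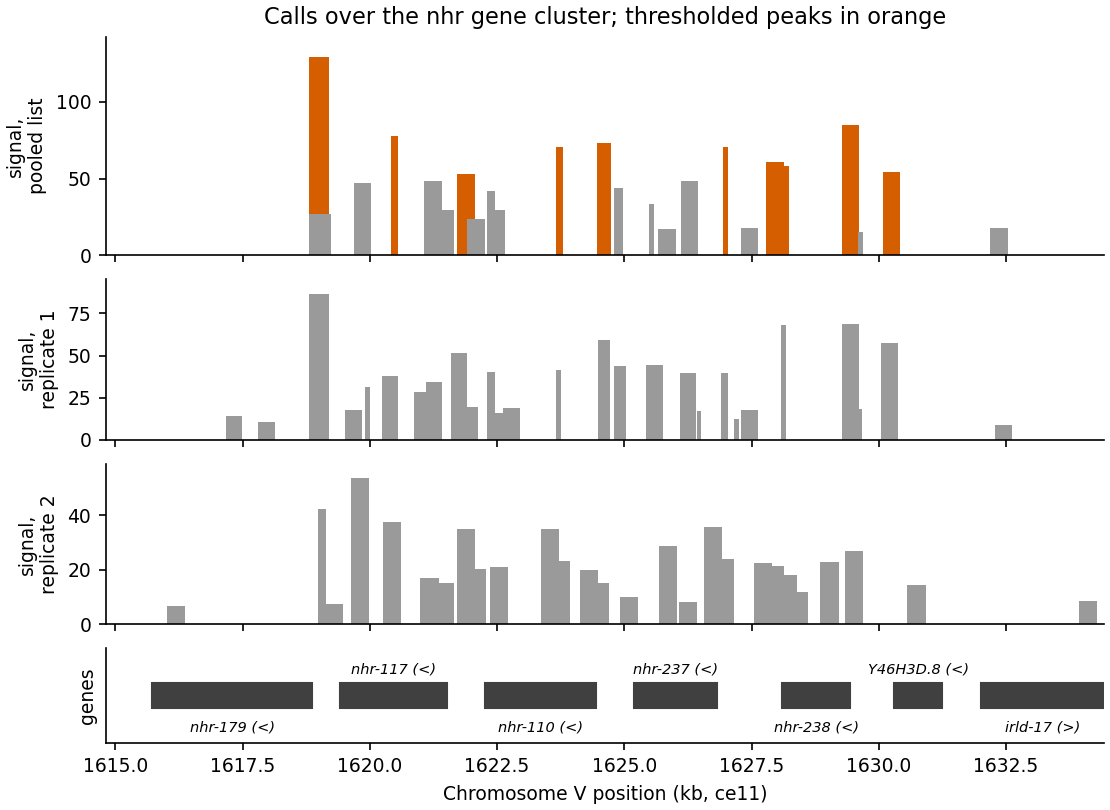
Calls on chromosome V around the nhr genes (x axis, kb on ce11) with their deposited signal values (y axes) in the pooled list, replicate 1 and replicate 2, above the protein-coding genes. Orange bars are the 10 thresholded peaks and grey bars other calls; arrows beside names give the strand.

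No thresholded peak was found near the gene whose product was tagged or near the marker gene named in the strain's genotype. ZK546.5 lies on chromosome II from 4935818 to 4937974, and the nearest thresholded summit was 83983 bp away. The gene unc-119, mutant in this strain, lies on chromosome III from 10902641 to 10908935, and the nearest thresholded summit was 53596 bp away. Within 20 kb of the 2 genes there were 0 of 261 thresholded peaks and 21 of 29710 other calls (two-sided Fisher's exact test, p = 1). With so few calls in these windows, the test could have shown an excess of peaks but not a shortfall. The strongest call in these windows had rank 797 in the pooled list, with a signal of 34.7, and lay by unc-119. The strongest by ZK546.5 had rank 2234.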

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

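The settings that used nuclear peaks alone, protein-coding genes alone, calls split by distance to a 5′ end, peaks outside the chromosome V cluster, or RNA gene lists against protein-coding genes were chosen after the data were seen. The closeness of peaks to gene 5′ ends kept its direction and its side of the threshold in all 12 alternatives, with odds ratios from 4.21 to 9.67, and GC content did so in all 10, with differences from 4.35 to 13.1 points. Overlap of the replicates stayed above random placement in all 10 settings tried (21.5% to 73.8% of calls), and their signal correlation kept a permutation p below 0.05 in all 5 (0.55 to 0.83). The alternative without peaks within 20 kb of ZK546.5 and unc-119 removed 0 of the 261 thresholded peaks. It is counted above but was no real test of closeness to 5′ ends, GC content or the correlation. A further correlation over the 16 mitochondrial peaks was 0.53. The share of peaks on X depended on the setting. Its odds ratio was 0.99 for the strongest 130 peaks, 0.70 against the strongest other calls, between 0.71 and 0.77 with either replicate left out, 1.66 among calls farther than 500 bp from a coding 5′ end, and 0.43, past the threshold, among calls within that distance. Among 2 times as many calls, replicate 1 held 81.2% and replicate 2 held 92.7% of the thresholded peaks, and among all calls 96.9% and 97.7%, as a larger list must hold at least as many. Against 4 gene lists in the main comparison, 2 passed with nearest-gene assignment, 5 at 1000 bp and 6 with the 5′ end of every annotated transcript. Without mitochondrial peaks chromosome III also passed, and no other chromosome changed its side. Of 2080 words of 6 bases, 440 were more frequent at peaks in the main comparison, 292 against the strongest other calls and 197 against matched calls. The number less frequent was 77 for the strongest 130 peaks, 69 against matched calls, and 73 to 166 with either replicate left out. For longer words more were tested, so their counts are not on the same base. Of 8192 words of 7 bases, 607 were more and 110 less frequent, and of 32892 words of 8 bases, 497 and 46. The cause of these shifts was not tested. Random positions keep the chromosome counts, so that comparison was not run for the share on X. Replicate overlap and correlation need both replicates, so neither could be left out there. No paired analysis was possible because there was 1 group. Depth was unknown, so weak binding that missed the threshold cannot be separated from absence of binding.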

Other observations

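The 3 patterns below, the look at spliced leader genes, the comparison of X with autosomes by distance to protein-coding 5′ ends, the cluster tests of background and replicate difference, and the comparison of ribosomal protein genes with other families were chosen only after the result was seen. Among the small RNA genes, the spliced leader genes were of interest because they supply the leader sequences added to many C. elegans messages. A thresholded summit lay within 500 bp of the 5′ end of 4 of the 19 sls-2 genes, sls-2.1 (signal 174), sls-2.4 (116), sls-2.3 (79.5) and sls-2.2 (79.5, the same peak), and of 0 of the 12 sls-1 genes. The difference between the sls-2 and sls-1 genes was not tested. Whether reads could be placed uniquely at the sls-1 genes was not examined, so their 0 is not evidence of absence. The 4 sls-2 genes were the only snRNA genes with a peak in a list of 129 (odds ratio 4.62, Fisher's exact test, adjusted p = 0.111). With replicate 1 alone, 5 of the 129 had one and the list passed the threshold (odds ratio 6.98, Fisher's exact test, adjusted p = 0.0166). For the 4 thresholded members set against protein-coding genes, the odds ratio was 2.90 (Fisher's exact test, adjusted p = 0.286). With nearest-gene assignment, 1 of the 129 snRNA genes had a peak (odds ratio 2.63), and the list did not pass the threshold.

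Peaks on X far from protein-coding 5′ ends. On X, 19 of 28 peaks lay more than 500 bp from a protein-coding 5′ end (67.9%), against 50 of 207 on autosomes (24.2%). The 12-base motif TCGCGCAGGGAG, recalled from general knowledge, not from a motif table, as that of sites recruiting the dosage compensation complex to X, was found with at most 2 mismatches within 200 bp of the summit at 11 of these 19 peaks (57.9%, 95% interval 33.5 to 79.7), at 2 of the 50 autosomal peaks, and at 30 of 5219 other pooled X calls (0.575%, Fisher's exact test, p = 1.13e-19). It matched exactly at the peaks with summits at 11094179 and 2997102, and the median distance from match to summit was 36 bp. Base composition alone did not account for this, as 0 of 100 scrambled versions of the motif occurred at as many of the 19 peaks and the most frequent occurred at 8. A hypothesis is that part of the ZK546.5 signal on X may come from dosage compensation sites, and whether such sites are also recovered with other tagged proteins or in a mock immunoprecipitation was not tested.

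Ribosomal protein genes. The values argue against 2 other readings as sole accounts of the 38.3% share with a peak. These are any gene 5′ end that can give a call, and close gene spacing. Among calls at protein-coding 5′ ends, thresholded peaks lay at ribosomal protein genes in 29 of 187 cases and other calls in 33 of 6135 (odds ratio 33.9, Fisher's exact test, p = 8.94e-29). Among genes with a coding neighbour within 1000 bp, 24 of 57 ribosomal protein genes had a peak (42.1%). Of the other such genes, 139 of 4643 had one (2.99%, odds ratio 23.6). That 2.99% was above the 1.07% of all other protein-coding genes, so close spacing may still add to the share. Signal at any abundantly transcribed family stays open, because no expression data were used here and the 6 other families compared do not settle it. All their shares lay below the lower 95% bound of 27.7% for ribosomal protein genes, but the upper bounds for translation factor (30.5%), heat shock protein (29.2%) and proteasome genes (28.2%) passed it, and those for respiratory chain (17.5%), muscle (9.25%, with collagen the only families in an earlier version of this test) and collagen genes (3.14%) did not. Recovery of such promoters in any immunoprecipitation from larvae also stays open, as no mock sample was used here.

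The cluster of peaks over nhr genes. Of the 10 summits in this 11613 bp stretch of chromosome V, 5 lay within 500 bp of a coding 5′ end (18.7% to 81.3%) and 161 of 225 other nuclear peaks did (71.6%), a test of ordinary promoter binding that was also run and left the question open. Reads shared with near-identical copies of at least 100 bp are argued against, as 0.904% of the stretch lay in such matches at 95% identity elsewhere. Shorter matches were not counted, so reads shorter than that are not covered. Raised background over the whole stretch stays open. Outside the thresholded peaks, other pooled calls covered 28.6% of it, above the 95th percentile of 20.7% in 10000 random nuclear windows. This cannot tell background from a dense run of peaks. The stretch was picked for its many peaks, and the random windows were not. The other calls included signals of 48.5, 48.2 and 47.4, just under the lowest of the thresholded set (51.5). A first version of this test counted the thresholded peaks themselves, so it was void and was replaced. A difference between the replicate cultures or libraries also stays open. The median log2 ratio of replicate 1 to replicate 2 signal was 1.03 over 9 peaks. That lay outside the range of -0.78 to 0.05 for equally many random other nuclear peaks. The 9 values are not independent, as the replicate 1 call at 1628097 served for both summits at 1627964 and 1628201. The random peaks were scattered while the cluster peaks are neighbours, so the range may be too narrow. The 16 mitochondrial peaks also had a tilt to replicate 1 (median 0.71). Nuclear peaks as a whole leaned to replicate 2 (-0.33 over 232 peaks, the cluster included, and -0.34 without it). Whether the cluster reflects binding at single promoters or something else was thus not settled. A change in copy number was not tested for lack of read depth.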
